A study of Drosophila melanogaster with 2 samples.

How the data were processed

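Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole embryos of 0 to 24 h from a line expressing CG30431 with a C-terminal GFP tag, per the labels. Chromatin was sheared by sonication to fragments of 200 to 800 bp and precipitated with an antibody against GFP, per the labels' protocols. The 2 samples are biological replicates of 1 group, from separate biosamples of the same donor line. Grouping followed the source label of each sample.

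The deposited files are peak lists on dm6 and dm3. Per the deposited readme, each replicate's list was derived from its alignment and a control alignment, a further list from both replicates pooled, and the reproducible list from these by the irreproducible discovery rate (IDR). The aligner, peak caller, their versions and the IDR threshold are not given in the sources used here. Each list that entered the IDR step holds 30000 entries, background included. Each peak carries the authors' signal value, whose scale is not stated, and the deposited −log10 of a q-value, which lay between 2.35 and 3.57 in the reproducible dm6 set. The signal is the peak's own value and was used only to describe, rank or filter peaks within a list. Signal values of the replicate and pooled lists were set side by side for the same peak, and those of the dm6 and dm3 sets by rank, without matching peaks. The lists may differ in read depth. No read counts were used here, so depth per sample is unknown. Most entries have a fixed width (364 bp for 75.3% of reproducible peaks), so widths carry little information. The reproducible set was tested against the pooled list and is exactly its 3314 strongest entries on dm6 and its 3245 strongest on dm3. On each build 2 intervals are listed again with a different summit, and all were kept as separate peaks.

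Main results used the reproducible dm6 set, with gene models of Ensembl release 115 (BDGP 6.54) and the matching genome sequence. Annotated transposable elements were not counted as genes, which left 18277 genes with 23694 distinct starts. A promoter peak had its summit within 500 bp of any annotated start. Other summits were assigned to 5' UTR, coding exon, 3' UTR, other exon, intron or intergenic sequence in that order. Random expectations came from 1000 placements of the summits within the same chromosome, and from 20 for transposable elements. Arms were tested by 1000 draws in proportion to length. With 1000 draws the smallest two-sided p is 0.0020. Signal at promoter and other peaks was compared by a two-sided permutation test with 100000 resamples. Agreement of replicates was the share of reproducible summits inside the 3314 strongest peaks of each replicate. The value of a peak in a replicate was that of the strongest entry holding its summit, and the strongest overlapping entry was looked up as well after the data were examined.

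The 21 gene lists and 18 motifs were fixed before the data were examined, as were the tests and the rule for named genes. The lists were cytoplasmic and mitochondrial ribosomal proteins, proteasome subunits, translation factors, splicing factors, replication-dependent histones, Hox genes, gap, pair-rule and segment-polarity genes, dorsoventral patterning genes, the Notch pathway and E(spl) complex, neuronal genes, muscle genes, germline genes, boundary and architectural proteins, Polycomb and trithorax group proteins, ZAD zinc-finger proteins, heat shock genes, cell cycle and replication genes, cuticle proteins, odorant and gustatory receptors, and yolk, larval serum and chorion proteins. Across the lists 5 names matched no gene symbol in the annotation used here. Each list was compared with all other protein-coding genes by two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 21 lists.

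Named genes were chosen by this rule. They are CG30431, then the 25 genes with a start nearest to, and within 500 bp of, the summits of the strongest reproducible peaks that also lie among the 3314 strongest of both replicates. From each list past the threshold the 3 members with the strongest peak are named, and so are the 5 strongest peaks with no start within 500 bp. The other members with a peak in the boundary protein list, elav and bcd were named after their values were seen.

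Motifs and 8-mers were counted in windows of 201 bp centred on summits, on either strand. Each peak had 5 control windows, at the same signed distance from the start of a random coding gene without a peak for promoter peaks, and at random positions of the same chromosome for the others, over 1000 bp from any summit. Motifs were tested by two-sided Fisher's exact test, and 8-mers one-sided on 2L, 3L and X, then again on 2R and 3R. Controls matched on GC kept the 5 of 50 draws per peak nearest in GC content.

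Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The tests were first run on simulated data of 3314 peaks. With random summits, 0 of 20 runs called any annotation class. With no sequence put in, 0 8-mers and 0 of 18 motifs were called, and 4 of 4 8-mers put into 5% of windows were recovered. The simulated windows and their controls were both drawn at random positions. The simulation therefore does not cover the difference in GC content between the real peak windows and their controls (36.0% against 41.3%). With 1 of 21 lists changed, 1 was called. An excess on X put in at 1.23 times was found at 1.27 times, and a log2 signal difference of 0.26 was found at 0.22.

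Alternatives were a stricter set (the 1657 strongest peaks), each replicate alone through its 3314 strongest peaks, the strongest pooled peaks, promoter windows of 200 and 1000 bp, starts of protein-coding genes, all genes as background, overlap rules, other window sizes and controls, and exchanged arms for the 8-mers. Controls matched on GC and an expectation by annotated starts were added after the data were examined. The dm3 lists were used only for the comparison of builds, since no dm3 reference was used here.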

Results

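CG30431 is a fruit fly zinc-finger protein of the zinc-associated domain (ZAD) family. Its sites on chromatin were mapped by ChIP-seq in whole Drosophila melanogaster embryos collected 0 to 24 h after laying, with both sexes pooled. The flies carried a transgene that fuses green fluorescent protein (GFP) to the C-terminus of CG30431, and chromatin was precipitated with an antibody against GFP. The series holds 1 group of 2 biological replicates, taken from separate biosamples of the same fly line. It has no second condition, so each comparison below sets the bound sites against the rest of the genome, or the replicates against each other. The reproducible set held 3314 peaks on genome build dm6, with deposited signal values from 70.8 to 1800 and a median of 121. The deposited files give no read counts, so the sequencing depth of each replicate is unknown and no interval that needs it is given. Intervals on shares of peaks or genes below are exact binomial intervals and cover only the number of peaks or genes counted.

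The replicates shared most of their strong sites. Of the 3314 reproducible peaks, 3003 (90.6%) had their summit inside the 3314 strongest peaks of replicate 1, and 2890 (87.2%) inside those of replicate 2. Randomly placed positions fell in these peaks in 0.823% and 0.814% of cases (1000 placements within the same chromosome, one-sided permutation p = 0.0010 for each, the smallest the placements can give). A total of 2607 peaks (78.7%) lay among the strongest of both replicates, and 28 lay among the strongest of neither. The reproducible set was itself derived from these lists, so this agreement is not independent of its making. Across the 3267 peaks with a value in both replicates, Spearman's rho of the signal values was 0.777 and Pearson's r of their log2 values was 0.845. Within the strongest peaks (817, those with a pooled signal of at least 189) rho was 0.806, but within the weakest (804, pooled signal from 70.8 to 90.4) it was -0.597. The pooled signal is close to the sum of the replicates' values, so within so narrow a range a high value in either replicate goes with a low value in the other. The negative rho follows from this selection and says nothing on how well weak peaks agree. These are correlations across peaks, which are not independent replicates. The signal value was higher in replicate 1 by a median factor of 1.34. For 146 peaks (4.47%) the ratio lay more than 1 log2 unit from that median. At 36 of these a stronger entry of either replicate overlapped the peak without holding its summit, so part of the difference came from matching by summit. With the strongest overlapping entry, a choice made after these values were seen, 116 of 3302 peaks (3.51%) lay that far and rho was 0.806.

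**Figure D1:**
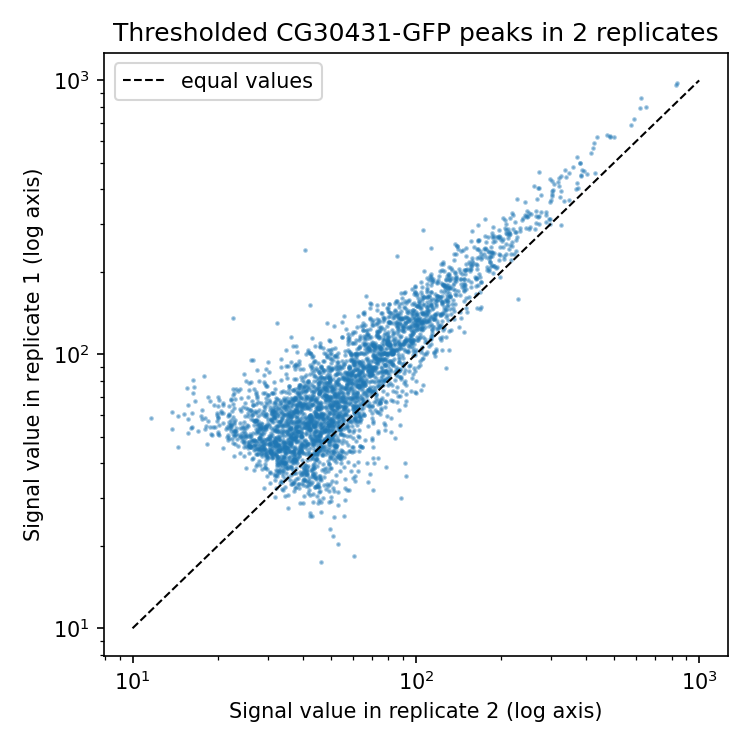
Deposited signal value of each reproducible peak in replicate 2 (x axis, log scale) against replicate 1 (y axis, log scale), 1 point per peak, for the 3267 peaks with a value in both. Most points lie above the dashed line of equal values, by a median factor of 1.34, and the scatter is widest among the weaker peaks.

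CG30431-GFP sites were concentrated at promoters and almost absent from coding sequence. The question of where in the genome the protein bound was addressed by placing each summit in the annotation. A summit lay within 500 bp of an annotated transcription start in 1466 of 3314 peaks (44.2%), against 13.6% ± 0.588 (SD over 1000 random placements), a ratio of 3.26. Coding exons held 10 summits (0.302%), against 13.7% at random. The 3' UTRs held 23 summits (0.694% against 4.46%), and 5' UTRs beyond the promoter window held 14 (0.422% against 0.776%). Introns held 1232 summits (37.2% against 39.5%) and intergenic sequence 536 (16.2% against 27.2%), both below the random share. These 6 classes differed from random placement after Benjamini-Hochberg adjustment over 7 classes (two-sided permutation, adjusted p from 0.0035 to 0.026). Exons of other kinds did not (33 summits, 0.996% against 0.804%, adjusted permutation p = 0.246). With a window of 200 bp the promoter share was 28.9%, against 6.15% at random. The 5' UTR class was not called in the strongest 1657 peaks or without replicate 2 (adjusted permutation p of 0.070 and 0.054), although its shares of 0.362% and 0.453% hardly moved.

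**Figure D2:**
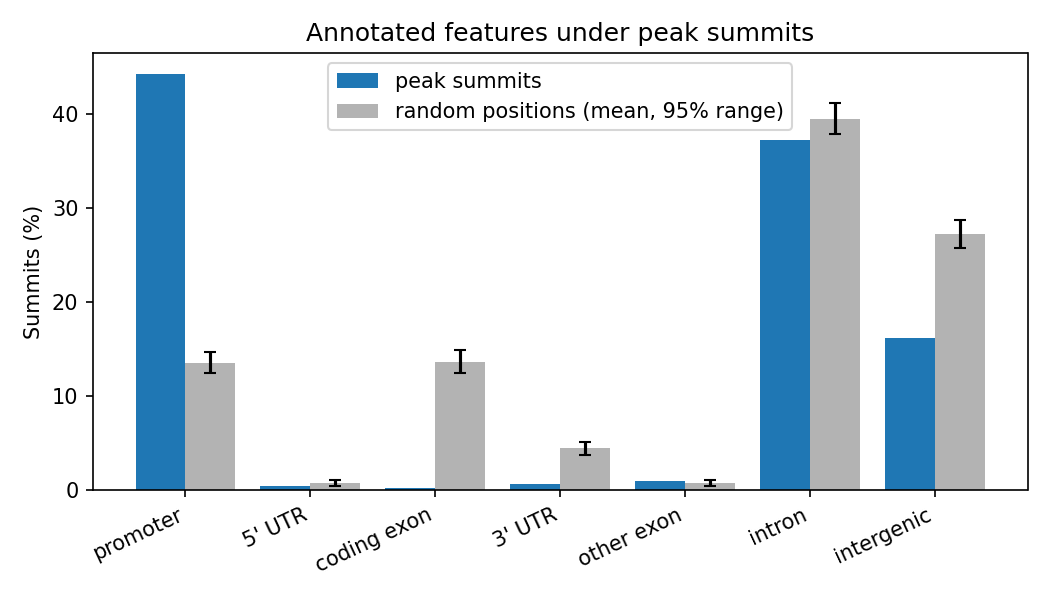
Share of the 3314 peak summits in each annotated class (blue bars) and mean share of 1000 random placements within the same chromosome (grey bars, with their 95% range). Promoters held 44.2% of summits against 13.6% at random, and coding exons 0.302% against 13.7%.

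Stronger peaks lay at promoters more often. The promoter share was 57.7% (95% interval 54.3 to 61.1) in the 828 peaks with the highest signal and 34.5% (31.3 to 37.8) in the 829 with the lowest. The median signal value was 137 at the 1466 promoter peaks and 111 at the 1848 others. The difference of median log2 signal was 0.30 (two-sided permutation test, 100000 resamples, p = 1e-05, the smallest they can give). With a promoter window of 200 bp the difference was 0.19. Peaks are not replicates, so this p describes the list rather than the spread between embryo collections.

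Promoter summits lay mainly just upstream of the start. Of the 1466 promoter summits, 1212 (82.7%, interval 80.6 to 84.6) were upstream of the nearest start, with a median position of -117 bp and quartiles of -221 and -44.2 bp. The fullest 20-bp bin was centred on -70 bp and held 118 peaks.

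**Figure D3:**
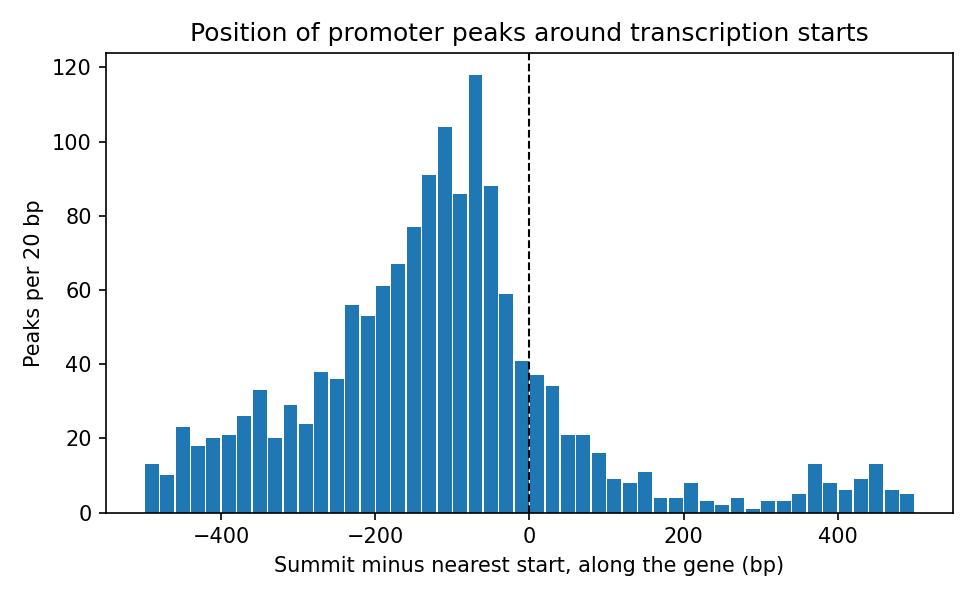
Number of promoter peaks per 20 bp (y axis) by the position of the summit relative to the nearest annotated transcription start, counted along the direction of the gene in bp (x axis, negative values upstream). The 1466 peaks cluster upstream of the start, with the highest bin of 118 peaks at -70 bp.

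The strongest promoter peak lay at Ugalt, a UDP-galactose transporter gene on X, with its summit at position 2703890 (peak 2703705 to 2704063), 38 bp upstream of the start. Its signal value was 1800 in the pooled data, 977 in replicate 1 and 833 in replicate 2, and it ranked first in both replicates. The next peaks lay at CG14100 on 3L (1786 pooled, 962 and 831 in the replicates) and at Chro on 3L (22878714 to 22879084). Chro encodes the chromodomain protein Chromator, and its values were 1484 pooled, 861 in replicate 1 and 622 in replicate 2. The peak at ph-p, a Polycomb group gene on X, had values of 1433, 799 and 648, with its summit 493 bp upstream of the start. The peak at px (plexus, a wing vein gene) on 2R had values of 1414, 794 and 619, and that at CG1888 on 2R had 1308, 720 and 590.

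Several of the other strong promoters belong to genes of mitochondrial RNA and protein metabolism. The peak at PNPase, a polynucleotide phosphorylase gene on 3R, had a pooled signal of 1120. The mitochondrial protease gene Lon had 774, and the mitochondrial ribosomal protein genes mRpL41 and mRpL23 had 794 and 742. No test was made of this group as a theme, and the full list of mitochondrial ribosomal proteins is given below. Other named promoters were Tcs5 (1056), the arginine methyltransferase gene Art3 (1008), tank (986), the adaptor gene Shc (884), CG5098 (858), CenG1A (853), CG13921 (839), CG9147 (839), the RNA-binding protein gene larp (809), CG5611 (787) and CG31145 (733), all as pooled signal values. The remaining 4 of the 25 named starts were of non-coding RNAs: lncRNA:CR44619 (812), asRNA:CR45928 (770), lncRNA:CR44339 (735) and lncRNA:CR31044 (729). In each replicate all 25 peaks ranked among the 59 strongest.

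The 5 strongest peaks away from any start lay in introns or between genes. The highest was in an intron of ush on 2L (480913 to 481258), 1393 bp from the nearest start, that of cbt. Its signal was 1254 pooled, 688 in replicate 1 and 576 in replicate 2. Intronic peaks followed in Lk6 on 3R (11760902 to 11761203, 1115 pooled) and in CG11050 on 2L (6612550 to 6612883, 1105 pooled). An intergenic peak on 2R (13035180 to 13035494, 1104 pooled) lay 11908 bp from the nearest start, that of CG13323. The last was in an intron of CG32772 on X (4910184 to 4910536, 961 pooled).

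Genes of cytoplasmic ribosomal proteins carried CG30431-GFP peaks far more often than other genes. A summit lay within 500 bp of a start in 55 of 90 of them (61.1%, interval 50.3 to 71.2), against 12.5% of the other protein-coding genes (two-sided Fisher's exact test, adjusted p = 8.36e-26 over 21 lists). In the strongest 1657 peaks the share was 38.9%, and it was still called. Over all 13968 protein-coding genes, 1784 (12.8%) had such a summit. The strongest peaks of this list were at RpS27 on 3R (25247388 to 25247649, pooled signal 561, summit 7 bp upstream), RpL7 on 2L (493, 32 bp downstream) and RpL23A on 3L (399, 79 bp upstream). Their values in replicates 1 and 2 were 317 and 246, 276 and 215, and 210 and 189.

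Genes of boundary and architectural proteins, which organise chromosome domains, also carried peaks more often. Of 17 such genes, 8 had a peak (47.1%, interval 23 to 72.2, adjusted Fisher p = 0.0024). In the strongest 1657 peaks the share was 29.4% (adjusted Fisher p = 0.031). The genes were Chro, Cp190, M1BP, Trl, pzg, Dref, BEAF-32 and CTCF. The peak at Cp190 on 3R (15275242 to 15275541) had a signal of 384 pooled, 240 in replicate 1 and 148 in the strongest overlapping entry of replicate 2. That entry does not hold the pooled summit, and the entry of replicate 2 that does has a value of 40.7. That at M1BP on 3R (8731941 to 8732105) had 241 pooled, 113 in replicate 1 and 123 in replicate 2. M1BP is also a member of the ZAD list.

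Chemosensory receptor, cuticle and histone genes had no CG30431-GFP summit within 500 bp of a start. Such a summit lay at none of 119 odorant and gustatory receptor genes (upper limit 3.05%, adjusted Fisher p = 1.24e-06). It lay at none of 102 cuticle protein genes (upper limit 3.55%, adjusted Fisher p = 8.02e-06) or 111 replication-dependent histone genes (upper limit 3.27%, adjusted Fisher p = 2.98e-06). By any overlap of the peak with the window, 0.840% of the receptor genes had a peak. The share was the same for summits within 1000 bp. The histone genes are near-identical repeated copies, in which reads are hard to place, so their count of 0 is uncertain. The test and the upper limit also count each copy as an independent gene, so both overstate the evidence for this list.

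The remaining 16 lists did not pass the test. Among these the highest share was in the ZAD family, to which CG30431 belongs (5 of 17, 29.4%, adjusted Fisher p = 0.131). The next were the Notch pathway and E(spl) complex (6 of 21, 28.6%, adjusted Fisher p = 0.128), Polycomb and trithorax group proteins (7 of 25, 28.0%, adjusted p = 0.115) and muscle genes (4 of 19, 21.1%, adjusted p = 0.409). Mitochondrial ribosomal protein genes had 15 of 73 (20.5%, adjusted Fisher p = 0.131), cell cycle and replication genes 6 of 31 (19.4%), translation factors 10 of 52 (19.2%) and heat shock genes 3 of 18 (16.7%). Germline genes had 2 of 15, splicing factors 3 of 24, neuronal genes 1 of 20 (elav), proteasome subunits 2 of 40, and gap, pair-rule and segment-polarity genes 1 of 30 (bcd). No peak lay at 8 Hox genes, 21 dorsoventral patterning genes or 13 yolk, larval serum and chorion genes. For these short lists a count of 0 still allows a share of up to 36.9%, 16.1% and 24.7%.

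**Figure D4:**
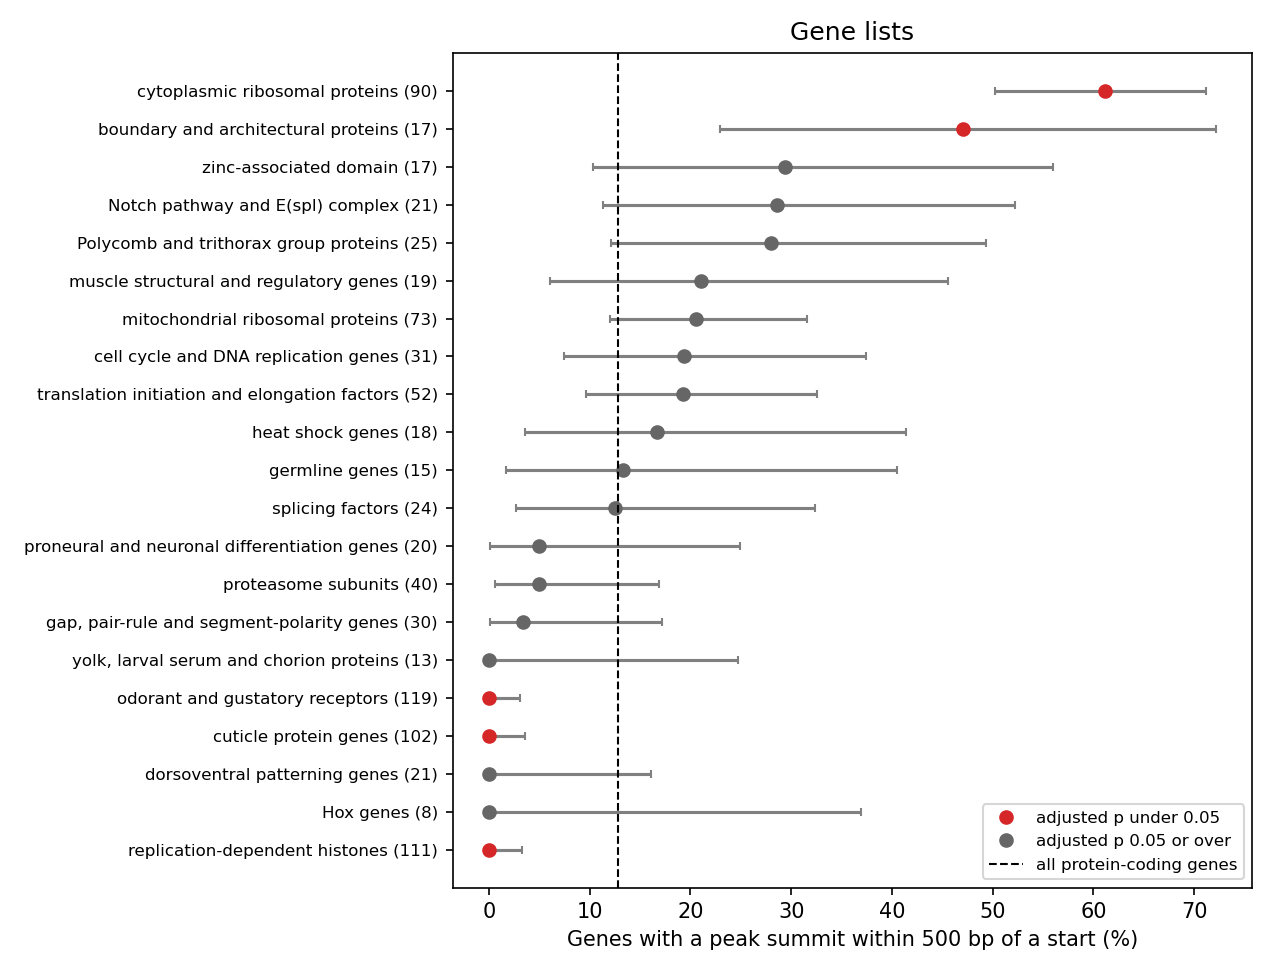
Percentage of the genes in each list with a peak summit within 500 bp of a transcription start (points, x axis), with exact 95% binomial intervals and the number of genes in brackets. Red points mark lists with an adjusted p under 0.05, and the dashed line is the 12.8% of all protein-coding genes.

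Short sequences built on CACTG were more frequent at the sites than in control windows. All 32896 8-base sequences (8-mers, both strands merged) were compared between windows of 100 bp on each side of the summits and matched control windows. On arms 2L, 3L and X, 785 were more frequent at summits, and 458 of these were again more frequent on 2R and 3R (one-sided Fisher's exact test, adjusted p under 0.05). CACTG, on either strand, occurred in 50 of the 458 (10.9%), against 0.778% of all 8-mers, and in 15 of the 20 with the lowest p. This core was not among the motifs fixed in advance, so these counts describe the list and do not test it. CACTG itself lay in 51.0% of peak windows, against 30.6% of control windows. The leading 8-mer, CACTGTGC, lay in 193 windows (5.82%) against 0.748% of control windows. CACAGTGG followed with 192 windows (5.79% against 0.815%), CACTGAGA with 157 (4.74% against 0.525%) and TACACTGA with 139 (4.19% against 0.573%). CACTGTGC and the reverse complement of CACAGTGG share CACTGTG. CACTGAGA and TACACTGA share CACTGA. The same site can therefore count under both 8-mers that share a stretch. Together the 4 lay in 474 windows (14.3%), against 2.21% of controls. A further 109 of the 458 consisted of A and T alone, and peak windows had a GC content of 36.0% against 41.3% in controls. In windows of 50 bp on each side the leading 4 lay in 1.56% to 2.11% of peaks on 2L, 3L and X, and all were still called. Against controls matched on GC as well, an alternative added after the data were examined, 148 8-mers passed.

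CACTGAGA and TACACTGA lay at promoters less often than elsewhere. CACTGAGA lay in 6.76% of peaks away from promoters and 2.18% of promoter peaks (two-sided Fisher's exact test, adjusted p = 1.13e-09). TACACTGA did likewise (5.79% against 2.18%, adjusted Fisher p = 2.61e-07). For CACTGTGC (6.33% against 5.18%, adjusted Fisher p = 0.215) and CACAGTGG (6.06% against 5.46%, adjusted p = 0.501) no such difference was detected. The former 2 and the latter 2 were taken as pairs after these values had been seen, so no test of the difference between the pairs is given. Members of both pairs occurred together in 8 peaks, where 18.9 would be expected from their separate frequencies (two-sided Fisher's exact test, p = 0.0041).

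The 8-mers lay to 1 side of the summit rather than on it. This was measured only after their profile around summits had been seen. The direction of reading was chosen on 2L, 3L and X and the side was then counted on 2R and 3R, although the 8-mers had been picked with all 5 arms. Read as CACTGTGC, 71 of 80 matches within 100 bp lay downstream of the summit (88.8%, interval 79.7 to 94.7). Read as CCACTGTG, the reverse complement of CACAGTGG, 79 of 88 did (89.8%). Read as TCTCAGTG 61 of 70 did (87.1%), and read as TCAGTGTA 42 of 48 did (87.5%). Adjusted p of the exact two-sided binomial test ran from 2.08e-14 to 1.26e-07. Within 300 bp of summits on all arms, 47.4% to 62.0% of matches lay in the 100 bp that begin 25 bp downstream of the summit, and 3.33% to 5.84% in the mirrored band upstream. The limits of this band were also set after the profile had been seen. The CTCF core sequence, measured in the same way, lay downstream in 27 of 43 matches (62.8%, adjusted exact binomial p = 0.126).

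**Figure D5:**
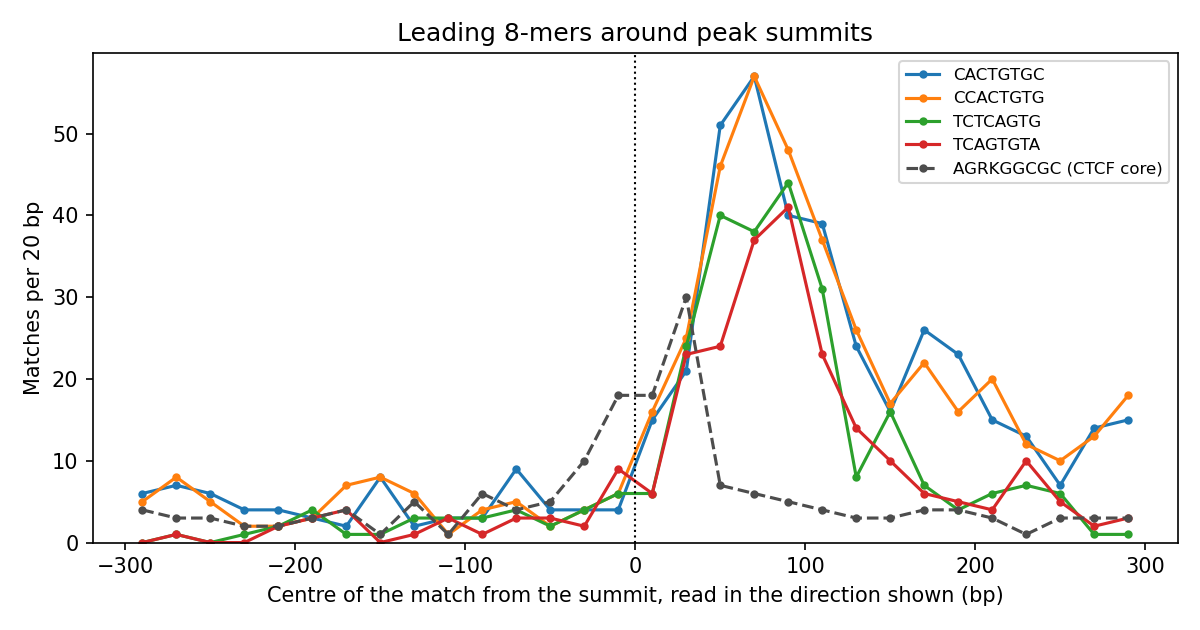
Number of matches per 20 bp (y axis) by the distance in bp from the peak summit to the centre of the match (x axis), each match read in the direction given in the legend, over all 3314 peaks. The 4 leading 8-mers concentrate in the 100 bp that begin 25 bp downstream of the summit, while the CTCF core (dashed grey) lies nearer to it on both sides.

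Of 18 known motifs fixed in advance, the core of the insulator protein CTCF was the most enriched against the controls matched on distance to a start. It lay in 90 summit windows (2.72%) against 0.507% of control windows (odds ratio 5.48, two-sided Fisher's exact test, adjusted p = 3.02e-25). With flanks at 500 bp as controls its odds ratio fell to 3.39, below the 4.99 of Motif 1. The core of the insulator protein su(Hw) lay in 34 (1.03% against 0.459%, adjusted Fisher p = 0.00076), and its call was lost in the strongest 1657 peaks and without replicate 1 (adjusted Fisher p of 0.287 and 0.087), where its odds ratio fell from 2.27 to 1.63 and 1.65. The Ohler 7 promoter element lay in 5.25% against 3.03% (adjusted Fisher p = 5.39e-09), with an odds ratio of 1.78 that rose to 2.86 with flanks as controls. The Pho core, bound by a Polycomb recruiter, was less frequent (26% against 33.2%, adjusted Fisher p = 1.18e-15). With controls matched on GC its odds ratio moved from 0.706 to 0.881. It was still called there (adjusted Fisher p = 0.0073), but much of the deficit went with GC content. The Ohler 6 element was also less frequent (0.332% against 0.754%, odds ratio 0.456, adjusted Fisher p = 0.011). Its call was lost in windows of 50 bp on each side, where the odds ratio of 0.473 was about as low. It was also lost in the strongest 1657 peaks (0.618), without replicate 1 (0.733) and without replicate 2 (0.571), and flanks as controls turned its direction.

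The calls of 4 other motifs depended on GC content. The TCT initiator (21.8% against 18.7%) and the A tract (14.8% against 10.7%) were more frequent, and the CA repeat (3.26% against 4.42%) and Zeste (23.9% against 26.2%) less frequent. With controls matched on GC the first 3 were no longer called (adjusted Fisher p of 0.437, 0.437 and 0.957), and Zeste turned to an excess (odds ratio 1.23). The calls were also lost for Zeste and the CA repeat in the strongest 1657 peaks (adjusted Fisher p of 0.083 and 0.061), where their odds ratios of 0.875 and 0.720 were no weaker than the 0.885 and 0.731 of all peaks. They were lost too for the CA repeat without replicate 2 (0.221) and for the TCT initiator in windows of 50 bp on each side (0.227). With flanks as controls the TCT initiator turned to an odds ratio of 0.945, which was not called, and the odds ratio of the CA repeat fell from 0.731 to 0.422. The other 9 motifs, among them DRE (4.35% against 5.15%, adjusted Fisher p = 0.090), GAGA (23.1% against 22.6%, adjusted p = 0.594) and Zelda (0.966% against 1.19%, adjusted p = 0.396), did not pass against the controls matched on distance. The results of some depended on the controls. With flanks at 500 bp DRE was more frequent at summits (odds ratio 1.962, adjusted Fisher p = 6.3e-08), and with controls matched on GC it was less frequent (0.654, 4.7e-06). GAGA went the other way (0.822, adjusted Fisher p = 0.00011, and 1.31, 5.3e-08). The longer GAGA motif did likewise (0.620 and 1.59), and BEAF CGATA turned from 1.29 with flanks to 0.909 with controls matched on GC (adjusted Fisher p = 0.044). No direction held across controls for these 4. Motif 1 and the TATA box (2.20) were more frequent with flanks as controls.

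Peaks were not spread over the chromosome arms by length alone. Chromosome 4 held 3 peaks, 0.0899 times the number expected by length, and 2R held 537 (0.858 times, both adjusted permutation p = 0.0060). The ratio on chromosome 4 was 0.150 without replicate 1, and 0.180 without replicate 2 and in the strongest 1657 peaks. X held 643 (1.10 times) and 2L 637 (1.09 times, both adjusted p = 0.018, permutation by length over 6 arms). The 713 peaks on 3L and 781 on 3R did not differ from expectation (adjusted permutation p of 0.559 and 0.599). Against the number of annotated starts 3L held an excess (1.12 times, adjusted permutation p = 0.0060), and 2L did not (0.986 times). The excesses on X and 2L were not called in the strongest 1657 peaks (both adjusted permutation p = 0.087), although the ratios there were no smaller, at 1.11 for each. The excess on 2L was not called without replicate 1 (adjusted permutation p = 0.252). Per 1000 annotated starts there were 165 peaks on X, 157 on 3L, 142 on 3R, 139 on 2L and 110 on 2R. The copy number of X in the pooled sexes was not taken into account.

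No reproducible peak lay in CG30431 itself (2R, 6202725 to 6205224) or within 5000 bp of it. The list of replicate 1 held a weak entry with its summit inside the gene (6204113 to 6204472, signal value 27, rank 6645), and the lists of replicate 2 and of the pooled data held none. The best pooled entry within 5000 bp ranked 10092, with a signal value of 35.0. The transgene adds copies of this locus, so its signal checks the labels only in part.

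The same experiment was deposited on the older build dm3, with 3245 reproducible peaks covering 1028971 bp, against 3314 peaks covering 1049303 bp on dm6. Each arm held slightly fewer peaks on dm3, for example 635 against 643 on X and 518 against 537 on 2R, except chromosome 4, with 3 on both. The signal values of the 100 strongest peaks, taken by rank, differed between builds by at most 0.315%. Coordinates were not converted between builds.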

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

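Entries outside the main measurement were found on the dm3 build, on heterochromatic or unplaced scaffolds outside the chromosome arms. The pooled list had 357 such entries, that of replicate 1 had 320 and that of replicate 2 had 417, each of 30000. These lists include background, so the entries need not be bound sites. The reproducible dm3 set had 1 such peak, counted in the comparison of builds, on 2RHet (1337603 to 1337966), with a signal value of 72.3 and rank 3183 of 3245. No dm3 annotation was used here, so what lies under these entries was not examined, and no explanation was tested.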

How the results depend on the processing

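The strongest pooled peaks are the reproducible set itself, so that setting is not counted here. The 19 other alternative settings, of which controls matched on GC and expectation by annotated starts were chosen after the data were examined, gave 251 values. Of the 50 for main comparisons, 45 kept their direction and side of the threshold, or stayed within 1.5 times for counts. The 45 include the agreement of each replicate with a set made from the same lists. They also include peak counts on the chromosome arms alone, where almost every peak lies. Those values could hardly change, so the 45 overstate how stable the results are. Among single results 179 were counted as doing so, 18 lost their call and 4 turned. The 179 include the ranks of the named promoter peaks in each replicate alone. Those peaks were chosen for lying among the strongest of both replicates. Their ranks could therefore not fail, and they say nothing on how stable the results are. The promoter share ran from 28.9% with a window of 200 bp to 55.2% with 1000 bp, above random in each. Without either replicate it was 43.6% to 44.5%, with 6 lists, 7 to 8 motifs, 3 to 4 arms and 399 to 474 8-mers called.

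5 counts moved. In the strongest 1657 peaks 2 arms were called rather than 4, with fewer peaks tested. The 458 8-mers became 136 in windows of 50 bp each side, 301 when found on 2R and 3R, and 148 with controls matched on GC. With flanks at 500 bp as controls 14 motifs were called rather than 9. The cause was not tested in these 4.

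Of the 4 single results that turned, none but Zeste was called in the new direction. With flanks as controls the odds ratio of Ohler 6 was 2.43 and that of the TCT initiator 0.945. With controls matched on GC that of Zeste was 1.23. Against annotated starts the ratio on 2L was 0.986. The cause was not tested. In addition, mitochondrial ribosomal proteins were called without replicate 1 (adjusted Fisher p = 0.0076), without replicate 2 (0.041) and against all genes (0.042), and Polycomb and trithorax group proteins with a window of 200 bp (0.011) and against all genes (0.042). The unknown depth limits what can be said of weak or missing peaks.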

Other observations

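Promoters bound by CG30431-GFP more often had starts on both strands nearby, whatever their arrangement. Such starts lay within 500 bp of the summit at 562 of 1466 promoter peaks (38.3%), against 25.3% of 7330 matched control positions (two-sided Fisher's exact test, p = 2.37e-23). Protein-coding genes had a peak at a start more often than genes of non-coding RNA. A gene counted by any of its annotated starts, and the number of starts per gene was not matched. The shares were 12.8% of protein-coding genes, 4.83% of 3289 ncRNA genes (adjusted p = 2.82e-44), 3.45% of 290 tRNA genes (adjusted p = 1.66e-07) and 4.09% of 269 snoRNA genes (adjusted p = 3.12e-06), by two-sided Fisher's exact test. Annotated transposable elements held 10 summits (0.302%), against 5.62% of randomly placed ones (20 placements). Reads from repeated elements are hard to place, so that count is uncertain. These comparisons were chosen after the data were examined.

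Among the explanations weighed next, the test of annotated starts on X and the one-sided profile of the 8-mers were chosen only after their results had been seen. The samples form 1 group, so no difference between groups was tested. Peak lists of embryos expressing GFP alone were not used here, so signal that any GFP precipitation gives at open promoters was not excluded for any pattern.

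The first pattern is the CACTG-core 8-mers. A lower GC content of peak windows is argued against, since the odds ratio of the 4 leading 8-mers together was 8.14 (95% interval 7.03 to 9.41) against controls matched on GC. Whether the 8-mers come from copies of transposable elements was not decided. Of the summits with any of the 4 in their window, 0 of 474 (0.0%, upper limit 0.775%) lay in annotated elements. That test placed the summit, whereas the 8-mers lay mainly beside it. Only 0.302% of all reproducible summits lay in annotated elements, where reads are hard to place. A low count was therefore likely whatever the origin of the 8-mers. A sequence preference with the summit on the recognised sequence failed its test: 4.14% of 748 matches (interval 2.83 to 5.83) lay within 10 bp of the summit, where an even spread gives 10.4%. Overlapping 8-mers at the same site count separately here, so the interval is too narrow. What also stays open is a hypothesis from the one-sided profile seen afterwards. Each pair of overlapping 8-mers may hold a fixed direction to the bound site, through a partner or a longer recognised sequence. The spacing to the summit was not fixed. Matches of CACTGTGC within 100 bp had offset quartiles of 34 and 74.5 bp, and those of CACTGAGA 32.25 and 82 bp. CACTG itself had no single direction, since the pairs carried it in opposite orientations.

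The second pattern is the peaks at cytoplasmic ribosomal protein genes. Close spacing of starts and short genes is argued against as the whole cause, since coding genes matched on both had a peak in 15.8% of cases on average, and in at most 31.1% over 10000 draws, against 61.1% in the list. The summits at these genes had a median position of -34.0 bp from the start (interval -47 to -25, 55 genes, 46 of them upstream). Only summits within 500 bp of a start were counted, and promoter summits of all genes lay mainly upstream too. Their position therefore cannot decide on signal from transcription through the gene body. Signal tied to high activity of these promoters themselves was not tested.

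The third pattern is the small excess on X. CA and GA repeats are argued against as the whole cause. Without the 316 peaks that hold such a repeat the ratio to length was 1.08 (permutation p = 0.036), against 1.10 with them. Other simple repeats were not tested. A larger number of annotated starts on X is argued against, since X held 165 peaks per 1000 starts (interval 152 to 177), against 137 on the large autosomal arms. Of those arms 3L alone held 157, inside that interval, so an excess by starts was not particular to X. The excess was not called in the strongest 1657 peaks, where its ratio was no smaller, at 1.11. X held 13.9% of the pooled entries outside the reproducible set, below its share of length (17.6%), against 19.4% of the reproducible peaks. Both sexes were pooled, and neither the expectation by length nor that by starts takes the copy number of X into account. The excess relative to the copies of X present was therefore not measured.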
